A study of Homo sapiens with 18 samples.

How the data were processed

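Messenger RNA was measured in 18 libraries of RPMI-8402, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line. The cells carried either a non-targeting control guide (NT) or a knockout of PIK3R1 (KO), the gene of a regulatory subunit of class I phosphoinositide 3-kinase (PI3K). Each genotype was treated for 24 h with the vehicle DMSO, with CB-103, an inhibitor of the NOTCH transcription complex, or with the gamma-secretase inhibitor LY3039278 (GSI). CB-103 and LY3039278 are not analogs of each other, and their doses are not given in the sources used here. The 6 groups held 3 replicates each. The labels do not say whether replicates were separate cultures. All p-values therefore measure only the spread between these libraries, part of which may be technical. Libraries were stranded, selected on polyA and read from both ends, per the labels' protocols.

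Expected counts per gene, rounded to whole numbers, were deposited by the authors in a single table of 58735 genes. Column totals of this table differed from the sums of the transcript estimates by at most 450 reads. For genes with a mean above 100 counts, the gene values differed from plain sums of the transcript estimates by a median of 2.84% and from length-scaled TPM by 0.481%. The step from transcripts to genes is not stated in the sources used here. Estimated counts per transcript and length-normalised values (TPM) were deposited for each library with effective lengths, per the file headers. A second gene table held variance-stabilised values on a log2 scale, as deposited. It was used for principal components and for a check of the first table, from which its log2 values differed above a mean of 5000 counts by a constant per library (SD at most 0.00228). The submitters' processing notes name bcl2fastq 2.20, FastQC 0.11.9, HISAT2 2.2.1, Salmon 1.4.0 and the build hg38, without their order or role. All 206601 transcripts matched GENCODE release 29, which supplied gene coordinates, and 58207 of the gene identifiers had a symbol in the name table.

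Totals per library ranged from 30416183 to 43558387 estimated reads. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 17346 genes, and libraries were scaled by trimmed mean of M values (TMM) with factors from 0.954 to 1.03. The common biological coefficient of variation was 0.0965. A quasi-likelihood F test (glmQLFit and glmQLFTest) was fitted to all 18 libraries with 1 mean per group, leaving 12 residual degrees of freedom. From this fit came 9 comparisons of 2 groups and 2 interaction contrasts, each the response of KO cells to an inhibitor minus that of NT cells. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE) unless a fold is given. Levels are library-scaled counts (CPM) as the mean with the SD over 3 libraries.

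Lists of genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. The preset correlation was 0.01, and adjustment ran over the lists within a comparison. The 27 lists, fixed before the data were examined along with the tests, the comparisons and the rule for naming genes, were these: NOTCH targets in T-ALL, ribosome biogenesis, nucleotide and polyamine synthesis, cytosolic ribosomal proteins, G1/S and DNA replication, G2/M and mitosis, G1 cyclins with their kinases and inhibitors, the BCL2 family, PI3K-AKT-mTOR components, FOXO targets, the amino acid response (ATF4), cholesterol synthesis, fatty acid synthesis, glycolysis, splicing factors, T-cell receptor and thymocyte markers, T-ALL transcription factors, MAPK feedback and immediate early genes, the interferon response, p53 targets, the AHR and NRF2 response, heat shock and chaperones, mitochondrially encoded genes, and markers of B cells, myeloid cells, erythroid cells and adherent cells. The erythroid list had 1 measured gene and was not tested, so 26 lists were tested in each of 11 comparisons, 286 tests in all. Camera was run again with the correlation estimated from the residuals. Calls of list members are also given with p-values adjusted over the list alone.

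Genes were named by a rule. It took 13 fixed genes (PIK3R1, HES1, HES4, DTX1, NRARP, NOTCH1, NOTCH3, MYC, IGF1R, IL7R, PTCRA, CDKN1B and CCND3). It added the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM, and up to 4 called members of each list. The rises and falls of 2-group comparisons were restricted to genes whose replicates did not overlap, which chance alone gives in 10% of cases for 3 libraries against 3. NRARP and PTCRA did not pass the count filter.

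Alternatives were DESeq2 size factors in the same edgeR test, the Wald test of DESeq2 1.42.0, limma-voom, no count filter, a fit to only the groups compared, the replicate number as a block, a threshold of 2-fold added to the adjusted p, gene sums of the transcript estimates, and leaving out each library in turn. Replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means. All 3 same-numbered pairs exceeded 0.1 in NT CB-103 and NT DMSO (0.521, 0.151 and 0.260), NT GSI and NT DMSO (0.302, 0.251 and 0.372), KO CB-103 and KO DMSO (0.543, 0.348 and 0.176), KO GSI and KO DMSO (0.493, 0.289 and 0.261), KO CB-103 and NT CB-103 (0.572, 0.171 and 0.118), and KO CB-103 and KO GSI (0.542, 0.227 and 0.270). A library of another number correlated higher for replicate 2 in NT CB-103 and NT DMSO (0.250) and in KO CB-103 and NT CB-103 (0.366). The pairing came from these values, since the labels give only the numbers. Deviations from a group mean cancel out, so a shift of replicate 1 alone makes replicates 2 and 3 deviate alike in every group. Values above 0.1 therefore do not show that replicates 2 and 3 were paired.

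The test was run on simulated counts for 17346 genes, drawn from the real mean levels, dispersions and library sizes, with 50 genes changed at each of 4 folds. Far fewer genes changed than were called in the data (109 calls against 10095 for NT CB-103 against NT DMSO), which made the adjusted threshold stricter. Libraries were drawn independently, without the difference of replicate 1. The shares below therefore hold for the simulated setting and not for the real comparisons. For NT CB-103 against NT DMSO, 18% of genes changed 1.25-fold, 48% at 1.5-fold, 60% at 2-fold and 82% at 4-fold were called, and 4.59% of calls were false. These shares were 22%, 44%, 74% and 88% for NT GSI against NT DMSO with 4.20% of calls false, and 36%, 54%, 74% and 86% for KO DMSO against NT DMSO with 6.02% false. For the CB-103 interaction they were 2%, 34%, 52% and 84% with 5.49% false, and for the GSI interaction 12%, 36%, 54% and 62% with 1.20% false. Correlations between responses were computed across genes for 9 pairs of comparisons, of which 6 are reported. The other 3 pairs, of knockout effects under different treatments, had not been planned and were dropped after they were computed. Unchanged groups against the same controls were simulated 20 times for the pairs that share DMSO libraries. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out. Replicates within groups differed by 5.30 to 72.6 times the variance that counting gives, and no library was a copy of another.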

Results

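PIK3R1 messenger RNA (chr 5, 68215720-68301821 in hg38) stood at 44.3, 45.5 and 42.5 CPM in the 3 NT DMSO libraries and at 23.1, 21.4 and 23.2 CPM in the 3 KO DMSO libraries. Under CB-103 it was 30.9, 33.5 and 29.1 CPM in NT cells and 25.9, 29.9 and 27.6 CPM in KO cells. Under GSI it was 50.7, 57.1 and 53.05 CPM in NT cells and 27.4, 32.2 and 23.9 CPM in KO cells. The gene thus fell by 1.96-fold in KO against NT cells under DMSO (log2 fold change -0.97±0.09 SE, n = 3 per group, edgeR adjusted p = 4.1e-07) and by 1.93-fold under GSI (-0.95±0.09, adjusted p = 3.9e-07). Under CB-103 the genotypes did not differ past the threshold (-0.16±0.09, adjusted p = 0.17), although gene sums of the transcript estimates gave -0.33 with an adjusted p = 7.6e-05. PIK3R1 itself had fallen with CB-103 in NT cells (-0.50±0.09, adjusted p = 7.4e-05) and risen in KO cells (0.31, adjusted p = 0.0088). The call in KO cells was lost without KO DMSO replicate 2 or KO CB-103 replicate 2. Its transcript with the widest span, the only 1 to reach 1 TPM in any library, stood at 9.93±0.46 TPM in NT DMSO and 4.98±0.20 TPM in KO DMSO. RNA of the gene therefore remained in KO cells, and protein was not measured here.

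**Figure D1:**
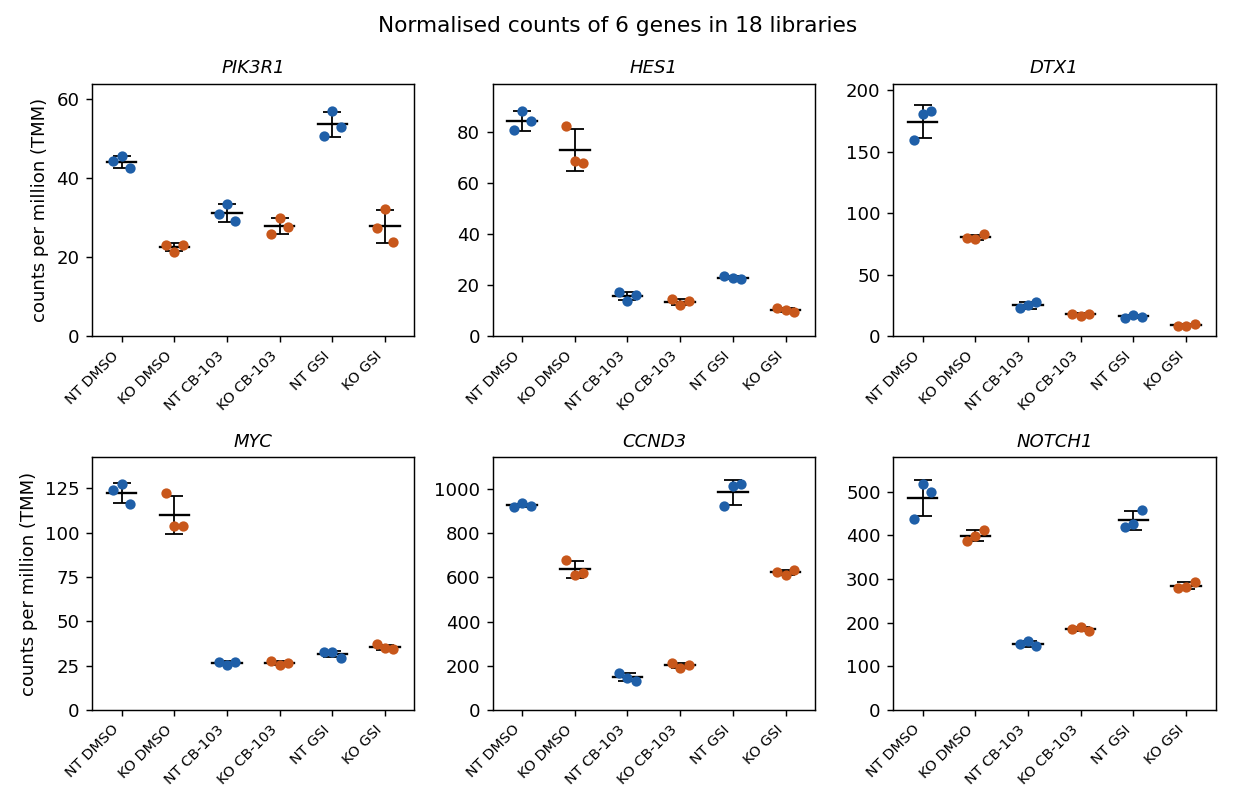
CPM of 6 genes in each of the 18 libraries (points), with group means (lines) and SD over 3 libraries (bars). Blue, NT cells; orange, KO cells. CCND3 lay lower in all CB-103 libraries than in the DMSO and GSI libraries of the same genotype, while MYC, HES1 and DTX1 lay lower with both inhibitors.

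Which libraries stood apart was asked before any gene was compared. The first 4 principal components of the 1000 most variable genes held 47.1%, 16.9%, 10.3% and 9.16% of the variance. Correlations within groups ranged from 0.992 to 0.994. The share of counts from mitochondrially encoded genes was lower in KO DMSO (1.79±0.094%) than in NT DMSO (3.34±0.33%), and stood at 5.23±0.43% in NT CB-103 and 2.24±0.41% in KO CB-103. In NT GSI it varied most, at 5.51%, 1.90% and 3.95% in replicates 1, 2 and 3, against 2.46±0.098% in KO GSI. Libraries of replicate 1 also differed from replicates 2 and 3 across the groups. In a fit with the group as a second term, 2488 genes passed the threshold between replicate 1 and the others, 1698 higher and 790 lower. Of the 114 genes at least 2-fold higher in replicate 1, 50 (43.9%) had at least 25% of their exons covered by a much more abundant gene on the opposite strand, against 1.46% of all genes tested. VIM-AS1, chosen after its value was seen, stood 3.12 higher in log2 units in replicate 1 and lies opposite VIM.

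Markers of other cell types were low. CD79B reached at most 2.85 CPM as the highest group mean, the erythroid and megakaryocytic ITGA2B 0.945 CPM, and the epithelial KRT8 0.434 CPM. CD68, a lysosomal protein used as a myeloid marker, reached 34.9±4.2 CPM in KO CB-103 from 3.53±0.58 in KO DMSO, and COL1A1 reached 22.3 CPM in NT GSI. The B-cell, myeloid and adherent lists did not pass the threshold with CB-103 in NT cells (camera adjusted p = 0.56, 0.78 and 0.69). Of the erythroid list only ITGA2B was measured, and it was not called (0.16±0.56).

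What CB-103 does in control cells was asked by comparing NT CB-103 with NT DMSO. NOTCH target genes fell together with the leukaemia drivers MYC and CCND3. DTX1, which encodes a NOTCH-bound ubiquitin ligase, fell 6.95-fold, from 175±13 to 25.1±2.7 CPM (-2.80±0.08, n = 3). HES1, a repressor switched on by NOTCH, fell 5.36-fold (84.4±3.9 to 15.7±1.7 CPM), and MYC fell 4.60-fold (122.5±5.8 to 26.6±0.90 CPM, adjusted p = 1.8e-14). CCND3, the D-type cyclin of developing T cells, fell 6.25-fold, from 926±7.5 to 148±19 CPM (adjusted p = 9.4e-15). NOTCH1 itself fell 3.21-fold (485±41 to 151±6.0 CPM) and NOTCH3 4.31-fold. Of 17346 genes tested, 10095 were called, 5120 higher and 4975 lower, and 3101 of them changed at least 2-fold. Among the 12 measured NOTCH targets, 11 fell, none rose and 1 did not pass (camera adjusted p = 1.2e-07, and adjusted p = 0.0064 with an estimated correlation). CR2 (-3.81±0.07) and RHOU (-2.62±0.06) were among the steepest of them. HES4 fell 3.09-fold and IGF1R 2.47-fold, while the cell cycle inhibitor CDKN1B rose 1.37-fold (0.46±0.05).

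Some genes induced by stress rose with CB-103 in NT cells. DDIT3, a transcription factor of the unfolded protein response, rose 28.5-fold, from 9.98±0.69 to 285±18 CPM (4.83±0.08). The neutrophil chemokine CXCL8 rose from 0.0937 to 22.4±4.2 CPM, CXCL3 rose 32.5-fold and MEI1 35.6-fold. The amino acid response (ATF4) list rose for 15 of 23 members and fell for 1 (2 adjusted over the list alone), with SLC7A11 at 4.26±0.12, ATF5 at 3.41±0.07 and TRIB3 at 3.28±0.09 (camera adjusted p = 8.8e-06, but adjusted p = 0.081 with an estimated correlation). Heat shock and chaperone genes rose for 8 of 13 and fell for 4, led by the endoplasmic reticulum chaperones HSPA5 (3.29±0.08) and HSP90B1 (2.50±0.06), at an adjusted p = 0.018, but adjusted p = 0.51 with an estimated correlation. All but 1 of 8 measured genes of the AHR and NRF2 response rose and none fell, among them the glutathione synthesis gene GCLM at 1.41±0.09 (adjusted p = 4.7e-04, but adjusted p = 0.081 with an estimated correlation).

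Sterol genes rose as a group. In the cholesterol list 17 of 20 rose and none fell, including STARD4 (2.22±0.07), HSD17B7 (2.04±0.08), the sterol sensor INSIG1 (2.03±0.06) and HMGCS1 (1.72±0.05). This list passed both ways (adjusted p = 2.6e-07, and adjusted p = 0.011 with an estimated correlation). Fatty acid synthesis rose for 6 of 10 and fell for 1, with SCD at 2.16±0.07 (adjusted p = 0.045, but adjusted p = 0.30 with an estimated correlation).

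Proliferation genes fell with CB-103 in NT cells. Of 27 genes of G1/S and DNA replication, 25 fell and 2 rose, with a median of -1.01. The replication genes UHRF1 (-2.32±0.07), RRM2 (-2.25±0.09), CCNE2 (-1.79±0.07) and PCNA (-1.68±0.06) fell most (adjusted p = 1.5e-10, but adjusted p = 0.14 with an estimated correlation). G2/M genes fell for 19 of 22 and rose for 1, TOP2A and CDK1 both by -0.86±0.05 (adjusted p = 8.6e-07, but adjusted p = 0.14 with an estimated correlation). G1 cyclins, their kinases and inhibitors fell for 7 of 12 and rose for 2, of which CDKN1A rose by 3.38±0.27 from a low level (adjusted p = 0.038, but adjusted p = 0.30 with an estimated correlation). Biosynthetic genes fell too. Ribosome biogenesis fell for 24 of 30 and rose for 3, with BOP1 at -1.67±0.05 (adjusted p = 5.1e-06, but adjusted p = 0.16 with an estimated correlation), and nucleotide and polyamine synthesis fell for 14 of 17 and rose for 1, with NME1 at -1.55±0.07 (adjusted p = 1.3e-05, but adjusted p = 0.12 with an estimated correlation). Glycolysis fell for 19 of 22 and rose for 2, with LDHA at -1.79±0.09 and HK2 at -1.56±0.08 (adjusted p = 8.3e-07, but adjusted p = 0.17 with an estimated correlation). Splicing factors fell for 23 of 35 and rose for 4, with SNRPF at -1.31±0.06 (adjusted p = 1.5e-05, but adjusted p = 0.24 with an estimated correlation). Ribosomal proteins fell for 12 of 36 and rose for 1, with RPL23 at -0.35±0.06 (adjusted p = 0.047, but adjusted p = 0.62 with an estimated correlation).

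Lineage genes lost expression as well. T-cell receptor and thymocyte markers fell for 18 of 24 and rose for 2, and the surface receptor CD2 went from 64.6±11 to 5.23±0.95 CPM (adjusted p = 1.9e-05, but adjusted p = 0.10 with an estimated correlation). T-ALL transcription factors fell for 15 of 17 and rose for 1, with LMO1 at -2.25±0.06 and MYB at -1.39±0.06 (adjusted p = 2.6e-07, but adjusted p = 0.10 with an estimated correlation). PI3K-AKT-mTOR components fell for 15 of 27 and rose for 6, and the lipid phosphatase INPP5D fell by -1.69±0.07 (adjusted p = 0.013, but adjusted p = 0.30 with an estimated correlation). The remaining lists did not pass. They were the BCL2 family (5 rose and 7 fell of 14, adjusted p = 0.34), in which BBC3 rose by 3.59±0.22 and BCL2 fell by 1.60±0.10, FOXO targets (7 and 7 of 20, adjusted p = 0.56), MAPK feedback (5 and 9 of 18, adjusted p = 0.062), p53 targets (7 and 6 of 17, adjusted p = 0.39) and mitochondrially encoded genes (1 and 0 of 13, adjusted p = 0.26). The interferon list (8 and 9 of 19, adjusted p = 0.94) had a median of -0.23 and a mean of -0.053 while camera ranked it upward.

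**Figure D2:**
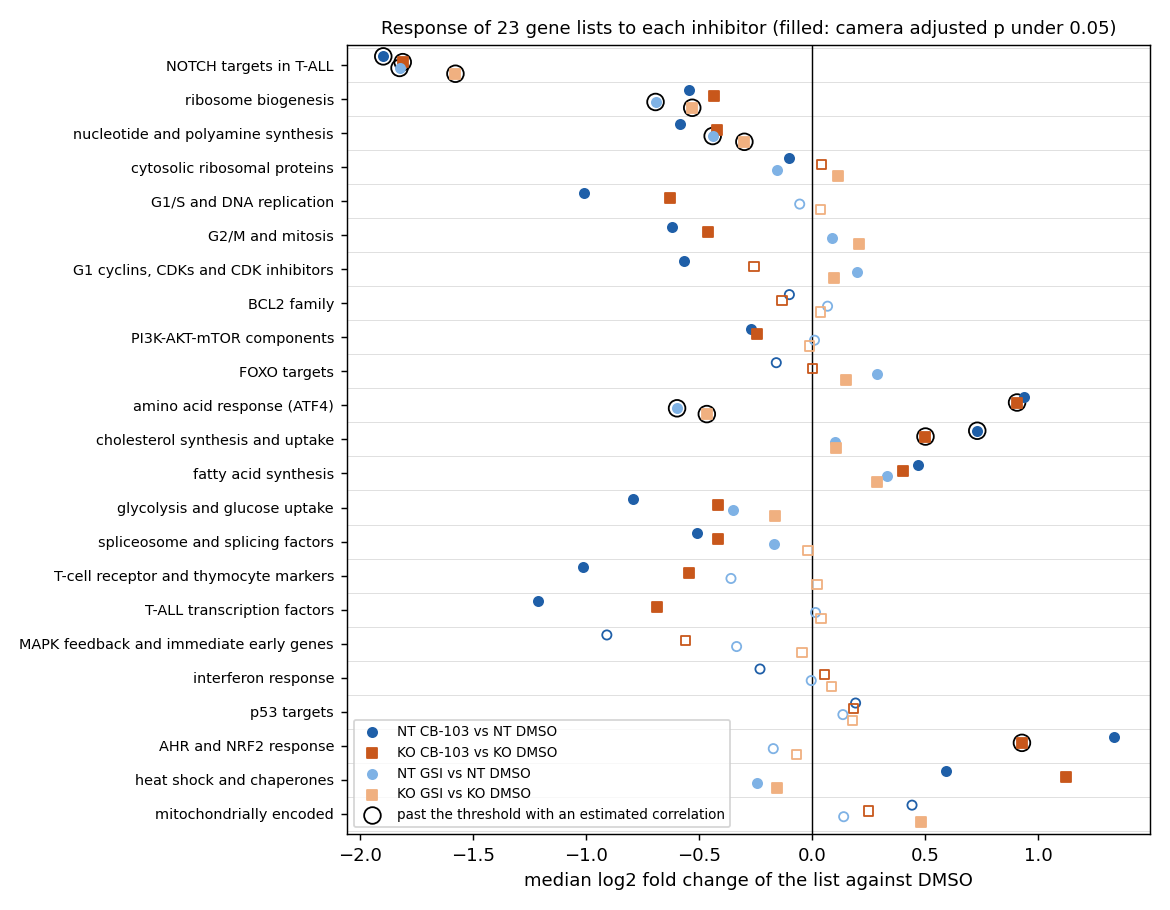
Median log2 fold change of 23 gene lists in the 4 comparisons of an inhibitor with DMSO. Filled points passed camera at the preset correlation; rings mark lists that also passed with an estimated correlation.

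How the gamma-secretase inhibitor compares was asked next, in NT GSI against NT DMSO. NOTCH targets fell, and CCND3 was not called. DTX1 fell 10.9-fold, from 175±13 to 16.02±1.1 CPM (-3.45±0.08, n = 3), HES4 from 49.5±1.0 to 4.51±0.13 CPM, HES1 3.68-fold and MYC 3.89-fold (122.5±5.8 to 31.5±1.7 CPM, adjusted p = 6.4e-13). CCND3 stayed at 985±55 CPM against 926±7.5 (0.09±0.07, adjusted p = 0.42). NOTCH1 missed the threshold (485±41 to 434±21 CPM, -0.16±0.06, adjusted p = 0.0502). It was called without NT DMSO replicate 1 (-0.23, adjusted p = 0.0056) or NT GSI replicate 3 (-0.20, adjusted p = 0.028), with DESeq2 size factors (adjusted p = 0.0494), the DESeq2 Wald test (0.0226), limma-voom (0.0471), the replicate block (0.0227) and in replicates 2 and 3 only (0.029). CR2 fell 31.7-fold, the muscle and stress gene ANKRD1 44.5-fold and OLFM4 16.7-fold. The lectin LGALS1 rose 5.51-fold (3.51±0.60 to 19.3±2.9 CPM), RHEX 4.15-fold and HEMGN 3.39-fold. GSI called 4277 genes, 1677 higher and 2600 lower, and 510 changed at least 2-fold. Of 12 NOTCH targets, 9 fell (11 adjusted over the list alone) and none rose (adjusted p = 1.2e-16, and adjusted p = 1.6e-04 with an estimated correlation).

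Biosynthetic and amino acid response genes fell with GSI in NT cells. All 30 measured ribosome biogenesis genes fell, with PPAN at -1.97±0.06 and NOP16 at -1.04±0.06 (median -0.69, adjusted p = 1.0e-27, and adjusted p = 0.0044 with an estimated correlation). Nucleotide and polyamine synthesis fell for 16 of 17 (17 adjusted over the list alone), including SRM (-0.77±0.06) and ODC1 (-0.70±0.07), at an adjusted p = 3.2e-14 and an adjusted p = 0.0091 with an estimated correlation. The amino acid response list, which rose with CB-103, fell for 20 of 23 (21 adjusted over the list alone) and rose for none, with SLC7A11 at -1.5±0.14, CHAC1 at -1.49±0.13 and the serine synthesis gene PSAT1 at -1.07±0.05 (adjusted p = 1.3e-17, and adjusted p = 0.0017 with an estimated correlation).

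Other lists moved less, and all that passed in NT GSI lost the call when the correlation was estimated. Glycolysis fell for 14 of 22 and rose for 1, with HK2 at -1.0±0.08 (adjusted p = 4.7e-05, but adjusted p = 0.35 with an estimated correlation). Splicing factors fell for 18 of 35 and rose for 1 (adjusted p = 2.2e-05, but adjusted p = 0.33 with an estimated correlation), ribosomal proteins fell for 12 of 36 (adjusted p = 1.1e-04, but adjusted p = 0.38 with an estimated correlation), and chaperones fell for 7 of 13, with HSP90AB1 at -0.57±0.06 (adjusted p = 0.0015, but adjusted p = 0.38 with an estimated correlation). FOXO targets rose for 10 of 20 and fell for 1, led by KLF2 at 1.5±0.37 and SESN3 at 0.70±0.09, while GADD45A fell (-1.12±0.10; adjusted p = 0.0020, but adjusted p = 0.14 with an estimated correlation). Fatty acid synthesis rose for 6 of 10, with FADS2 at 0.71±0.07 (adjusted p = 0.0036, but adjusted p = 0.23 with an estimated correlation). G2/M genes rose for 6 of 22, TOP2A by 0.28±0.05 (adjusted p = 0.0047, but adjusted p = 0.38 with an estimated correlation). G1 cyclins and inhibitors rose for 5 of 12 and fell for 1, the kinase inhibitor CDKN2C by 0.59±0.06 (adjusted p = 0.0094, but adjusted p = 0.31 with an estimated correlation). Cholesterol genes rose for 6 of 20 and fell for 3 (adjusted p = 0.027, but adjusted p = 0.26 with an estimated correlation). G1/S genes rose for 2 of 27 and fell for 4 (adjusted p = 0.69).

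The inhibitors were compared directly, first in NT cells. CCND3 separated them most among the 13 fixed genes, at 148±19 CPM with CB-103 and 985±55 with GSI, 6.64-fold lower with CB-103 (-2.73±0.08, n = 3, adjusted p = 7.1e-15). NOTCH1 was 2.87-fold lower with CB-103. HES4 was higher with CB-103 (16.02±2.0 against 4.51±0.13 CPM), and so was DTX1 (0.65±0.08), whereas HES1 (-0.54±0.09) and MYC (-0.24±0.07, adjusted p = 0.0056) were lower. SLC7A11 stood at 201±13 CPM with CB-103 and 3.67±0.96 with GSI, and DDIT3 at 285±18 and 8.42±0.79. AMIGO3 ran the other way (0.0919 against 8.12±0.92 CPM). In all 9765 genes were called, 5061 higher and 4704 lower with CB-103, of which 2768 differed at least 2-fold.

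NOTCH targets as a list did not separate the inhibitors in NT cells (4 higher and 4 lower of 12, adjusted p = 0.91), with a median of -0.19 and a mean of 0.054. The amino acid response did, with 21 of 23 higher under CB-103 and none lower (median 1.48, adjusted p = 3.4e-12, and adjusted p = 0.015 with an estimated correlation), as did cholesterol genes with 16 of 20 higher (adjusted p = 3.2e-06, and adjusted p = 0.021 with an estimated correlation). G1/S genes were lower for 24 of 27 and higher for 2, with RRM2 at -2.47±0.09 (adjusted p = 7.8e-11, but adjusted p = 0.18 with an estimated correlation). G2/M genes were lower for 20 of 22 and higher for 1 (adjusted p = 4.2e-08, but adjusted p = 0.18 with an estimated correlation). T-ALL transcription factors were lower for 15 of 17 and higher for 2, with LYL1 at -2.16±0.12 and ERG at -1.76±0.08 (adjusted p = 1.3e-05, but adjusted p = 0.18 with an estimated correlation).

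In KO cells the same comparison gave 8302 called genes, 4292 higher and 4010 lower with CB-103. CCND3 stood at 202±11 CPM with CB-103 and 623±10 with GSI (3.09-fold lower, -1.63±0.07, n = 3, adjusted p = 6.4e-12). HES1 was higher with CB-103 (0.41±0.10, adjusted p = 0.0019), opposite in sign to NT cells. SLC7A11 was 41.0-fold and JUN 27.0-fold higher with CB-103, and CASTOR1 4.24-fold lower. RGS16 stood at 6.39±0.42 CPM against 0.11±0.062. PIK3R1 was equal in these groups (0.00±0.09, adjusted p = 1.00). The amino acid response was higher for 21 of 23 (adjusted p = 2.7e-16, and adjusted p = 0.0044 with an estimated correlation) and cholesterol genes for 15 of 20 (adjusted p = 4.6e-06, and adjusted p = 0.024 with an estimated correlation). G2/M genes were lower for 21 of 22 and higher for 1, with CENPF at -1.07±0.05 (adjusted p = 1.6e-10, but adjusted p = 0.11 with an estimated correlation).

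The responses of PIK3R1 knockout cells were asked next. With CB-103 against DMSO, NOTCH genes fell in KO cells too, although DTX1 and NOTCH1 fell less than in NT cells, as the interaction below shows. HES1 fell 5.41-fold (73.0±8.1 to 13.5±1.1 CPM, -2.43±0.09, n = 3), DTX1 4.57-fold (80.5±2.2 to 17.6±0.89 CPM) and MYC 4.15-fold (110±11 to 26.5±1.1 CPM, adjusted p = 9.1e-14). CCND3 fell 3.15-fold (636±37 to 202±11 CPM) and NOTCH1 2.15-fold (399±13 to 186±4.6 CPM). CXCL8 rose from 0.189 to 93.8±9.3 CPM, DDIT3 22.6-fold and CLU 30.3-fold. There were 8432 called genes, 4322 higher and 4110 lower, of which 1712 changed at least 2-fold. NOTCH targets fell for 11 of 12 (adjusted p = 4.5e-10, and adjusted p = 0.0020 with an estimated correlation). The amino acid response rose for 20 of 23 and fell for none (adjusted p = 2.4e-11, and adjusted p = 0.0066 with an estimated correlation), cholesterol genes rose for 16 of 20 (adjusted p = 3.7e-08, and adjusted p = 0.0066 with an estimated correlation), and all 8 genes of the AHR and NRF2 response rose (adjusted p = 5.8e-05, and adjusted p = 0.031 with an estimated correlation).

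Cell cycle and chaperone genes also moved with CB-103 in KO cells. G1/S genes fell for 23 of 27 and rose for 2, with UHRF1 at -1.39±0.07 and RRM2 at -1.21±0.08, while CDC6 (1.10±0.08) and MCM5 rose (adjusted p = 2.8e-10, but adjusted p = 0.13 with an estimated correlation). Chaperones rose for 10 of 13 and fell for 2, with HSPA5 at 3.16±0.08 (adjusted p = 1.8e-05, but adjusted p = 0.23 with an estimated correlation). Ribosome biogenesis fell for 25 of 30 and rose for 2 (adjusted p = 2.4e-08, but adjusted p = 0.11 with an estimated correlation), and T-ALL transcription factors fell for 15 of 17 and rose for 1, with LMO1 at -2.44±0.06 (adjusted p = 5.6e-07, but adjusted p = 0.11 with an estimated correlation).

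With GSI, KO cells showed the same split between NOTCH targets and CCND3. HES1 fell 7.17-fold (73.0±8.1 to 10.2±0.73 CPM, -2.84±0.09, n = 3), DTX1 8.88-fold and MYC 3.10-fold (110±11 to 35.4±1.4 CPM, adjusted p = 9.7e-12). CCND3 did not change (623±10 against 636±37 CPM, -0.03±0.07, adjusted p = 0.84). NOTCH1 fell too (-0.49±0.06). LGALS1 rose 4.0-fold and RHEX 3.11-fold, and ANKRD1 fell 27.0-fold and CR2 21.6-fold. GSI called 3341 genes in KO cells, 1680 higher and 1661 lower, of which 322 changed at least 2-fold, 120 higher and 202 lower. Without a count filter 1259 were higher and 1785 lower. NOTCH targets fell for 10 of 12 (adjusted p = 3.0e-21, and adjusted p = 4.1e-05 with an estimated correlation). Ribosome biogenesis fell for 26 of 30 (28 adjusted over the list alone; adjusted p = 6.1e-24, and adjusted p = 0.0080 with an estimated correlation) and the amino acid response for 18 of 23, with SLC7A11 at -1.34±0.13 and CHAC1 at -1.28±0.13 (adjusted p = 1.3e-16, and adjusted p = 0.0023 with an estimated correlation). Nucleotide synthesis fell for 12 of 17 (adjusted p = 1.5e-09, and adjusted p = 0.038 with an estimated correlation). G2/M genes rose for 14 of 22 (15 adjusted over the list alone), CENPA by 0.38±0.06 and CDK1 by 0.31±0.05 (adjusted p = 9.8e-07, but adjusted p = 0.22 with an estimated correlation). Ribosomal proteins had fallen for 12 of 36 in NT cells. In KO cells they rose for 5 of 36 and fell for none (median 0.12, adjusted p = 6.5e-04, but adjusted p = 0.57 with an estimated correlation).

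**Figure D3:**
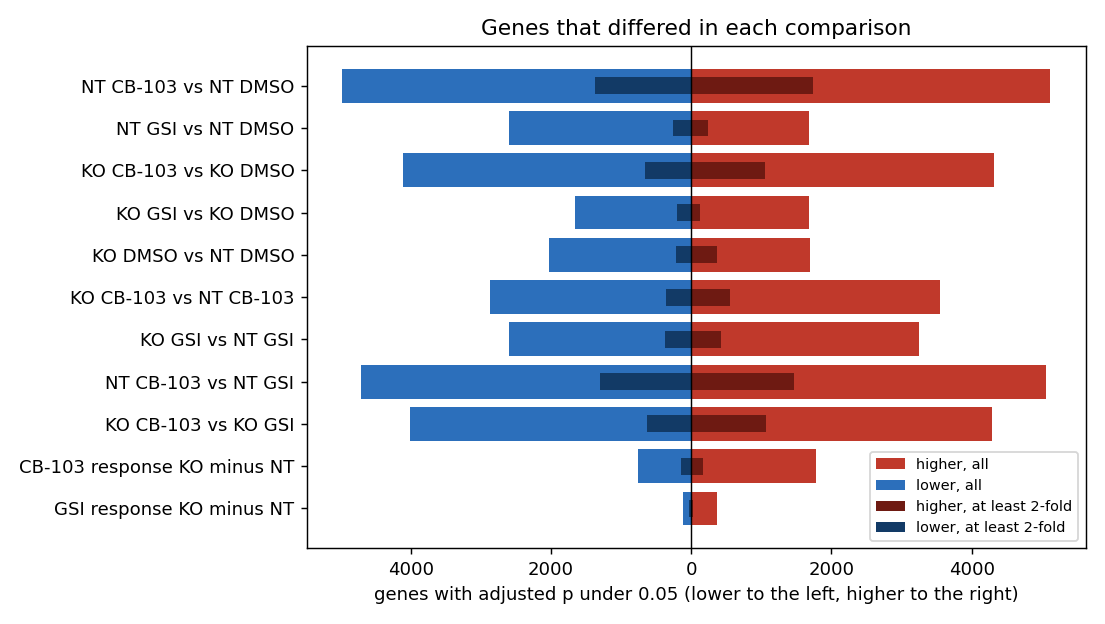
Genes called higher (to the right) and lower (to the left) in each of 11 comparisons. Darker parts are genes that changed at least 2-fold.

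What the knockout changes without inhibitor was asked in KO DMSO against NT DMSO. DTX1 fell 2.17-fold (175±13 to 80.5±2.2 CPM, -1.12±0.07, n = 3, adjusted p = 1.0e-08) and CCND3 1.46-fold (926±7.5 to 636±37 CPM, -0.54±0.07, adjusted p = 2.5e-05). NOTCH1 was lower as well (-0.28, edgeR adjusted p = 0.0015), a call lost on gene sums of the transcript estimates. The adhesion receptor CD44 fell 5.42-fold (92.7±2.3 to 17.1±0.41 CPM), the growth factor HBEGF 5.75-fold, ATP11A 5.76-fold and ZNF486 27.0-fold, and VASH1 went from 6.48±0.49 to 0.0284 CPM. FOXN4 rose 17-fold, TEAD4 13.9-fold, APBA2 11.1-fold and the homeobox gene HOXA10 11.1-fold, all from below 1 CPM. The T-cell gene CD7 rose (4.32±0.72 to 21.9±1.8 CPM). Of 17346 genes, 3720 were called, 1697 higher and 2023 lower, and 580 differed at least 2-fold, 363 higher and 217 lower. A single KO line was compared with a single NT line.

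Targets of NOTCH and of PI3K signalling moved in both directions with the knockout under DMSO. NOTCH targets rose for 3 of 12 and fell for 2 (adjusted p = 0.85), with HEYL up by 0.60±0.07. PI3K-AKT-mTOR components rose for 3 of 27 and fell for 7, with IRS2 at -0.81±0.13 and PIK3R3 at -0.41±0.06 (adjusted p = 0.56, median -0.016 and mean 0.0070). FOXO targets rose for 4 of 20 and fell for 6 (adjusted p = 0.39), with SESN3 at 0.95±0.09 and KLF2 at -2.79±0.45. Glycolysis fell for 6 of 22, LDHA by -0.82±0.09 and ALDOC by -0.75±0.11 (adjusted p = 0.057, and adjusted p = 0.87 with an estimated correlation). The replicate number as a block gave 0.022, although same-numbered libraries did not pair in this comparison. Only 2 lists passed camera. Mitochondrially encoded genes fell for 12 of 13, MT-ND1 by -1.30±0.27 (adjusted p = 2.1e-04, but adjusted p = 0.87 with an estimated correlation), alongside the lower mitochondrial share of the KO libraries. G1/S genes rose for 9 of 27 and fell for 2, E2F2 by 0.45±0.06 (adjusted p = 0.0098, but adjusted p = 0.87 with an estimated correlation).

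Under CB-103, KO cells expressed more of the proliferation and T-cell genes than NT cells. These differences include any already present under DMSO, where CD7 was also higher in KO cells. The interaction below takes the DMSO levels into account. RRM2 stood at 114±11 CPM in KO against 48.8±1.7 in NT cells (1.23±0.09, n = 3, adjusted p = 1.0e-08), UHRF1 at 215±15 against 102.8±12, and CCND3 at 202±11 against 148±19 (0.44±0.07, adjusted p = 1.3e-04). SEMA7A was 9.75-fold and CD48 6.82-fold higher, and MAP3K21 4.77-fold and HBEGF 3.86-fold lower. MYC was the same (26.5±1.1 against 26.6±0.90 CPM, adjusted p = 0.94). In all 6412 genes were called, 3547 higher and 2865 lower in KO cells, 926 at least 2-fold. Of 27 G1/S genes 23 were higher and 1 lower (adjusted p = 3.0e-11, but adjusted p = 0.28 with an estimated correlation). T-cell receptor and thymocyte markers were higher for 13 of 24 (15 adjusted over the list alone) and lower for none, with CD7 at 2.98±0.18 (adjusted p = 4.6e-05, but adjusted p = 0.26 with an estimated correlation). The BCL2 family was higher for 7 of 14 and lower for 1, BCL2 by 1.1±0.10 (adjusted p = 0.023, but adjusted p = 0.28 with an estimated correlation). MAPK feedback genes were higher for 6 of 18, ETV5 by 2.88±0.17 and SPRED2 by 2.58±0.15 (adjusted p = 0.030, but adjusted p = 0.26 with an estimated correlation). Mitochondrially encoded genes were lower for 12 of 13 (adjusted p = 8.8e-05, but adjusted p = 0.51 with an estimated correlation).

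Under GSI, HES1, DTX1 and NOTCH1 were lower in KO than in NT cells, while NOTCH targets as a list did not pass (5 higher and 3 lower of 12, adjusted p = 0.70, median 0.17 and mean -0.049). HES1 stood at 10.2±0.73 CPM in KO against 22.9±0.64 in NT cells (-1.17±0.09, n = 3, adjusted p = 6.8e-08), DTX1 at 9.07±0.79 against 16.02±1.1, NOTCH1 at 285±7.7 against 434±21 and CCND3 at 623±10 against 985±55. NOTCH3 was higher (0.85±0.17). HOXA10 was 16.7-fold and FOXN4 14.8-fold higher, KLF2 13.8-fold lower (0.454 against 6.32±0.60 CPM) and CD44 4.92-fold lower. Called genes numbered 5861, 3255 higher and 2606 lower, 797 at least 2-fold. Ribosomal proteins were higher for 29 of 36 (30 adjusted over the list alone) and lower for none, RPL11 by 0.47±0.10 (adjusted p = 5.6e-09, but adjusted p = 0.54 with an estimated correlation). Their share of counts was 8.66±0.46% in KO GSI and 7.31±0.57% in NT GSI, where it was 6.78%, 7.92% and 7.23% in replicates 1, 2 and 3, in the reverse order of their mitochondrial shares (5.51%, 1.90% and 3.95%). MAPK feedback genes were higher for 9 of 18 and lower for 2, ETV5 by 2.48±0.15 (adjusted p = 0.038, 0.060 with the replicate block, and adjusted p = 0.48 with an estimated correlation).

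Whether PIK3R1 loss changes the response to CB-103 was tested as an interaction. CCND3 fell less in KO cells, by 0.99±0.10 (n = 3 per group, adjusted p = 1.2e-05), as did NOTCH1 by 0.58±0.08 (adjusted p = 1.5e-04) and DTX1 by 0.60±0.11 (adjusted p = 0.0014). HES1 (-0.01±0.12, adjusted p = 0.97) and MYC (0.15±0.09, adjusted p = 0.33) did not differ between the genotypes. PIK3R1 itself differed by 0.81±0.13. The replication genes RRM2 (1.04±0.12) and UHRF1 (0.94±0.09), the survival gene BCL2 (0.92±0.13) and the homeobox gene MEOX1 (2.60±0.31) had fallen in NT cells and kept more of their expression in KO cells. The MAPK feedback genes SPRED2 (1.66±0.19) and ETV5 (1.5±0.23) did so as well, while the sterol genes HSD17B7 (-0.80±0.12) and STARD4 (-0.56±0.09) rose less. Of 17346 genes, 2533 differed, 1780 of them (70.3%) in the upward direction and 753 downward. At least 2-fold, 303 differed, of which 162 were upward and 141 downward.

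By list, this interaction was upward for 18 of 27 G1/S genes (21 adjusted over the list alone) and downward for 1 (median 0.38, adjusted p = 6.5e-11, but adjusted p = 0.25 with an estimated correlation). Glycolysis was upward for 15 of 22, PGK1 by 0.71±0.11 (adjusted p = 2.1e-08, but adjusted p = 0.25 with an estimated correlation). T-cell markers were upward for 9 of 24 (13 adjusted over the list alone), CD2 by 1.48±0.31 (adjusted p = 7.3e-05, but adjusted p = 0.25 with an estimated correlation). T-ALL transcription factors were upward for 7 of 17 (10 adjusted over the list alone; adjusted p = 3.2e-04, but adjusted p = 0.27 with an estimated correlation). Cholesterol genes were downward for 4 of 20 and upward for 1 (adjusted p = 0.0023, but adjusted p = 0.25 with an estimated correlation). Heat shock genes were upward for 7 of 13 and downward for 1 (adjusted p = 0.0023, but adjusted p = 0.41 with an estimated correlation). NOTCH targets did not pass (4 upward and 1 downward of 12, adjusted p = 0.090), with CR2 at 0.73±0.09. Neither did the amino acid response (7 and 3 of 23, adjusted p = 0.41), whose median was -0.031 and mean 0.014.

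**Figure D4:**
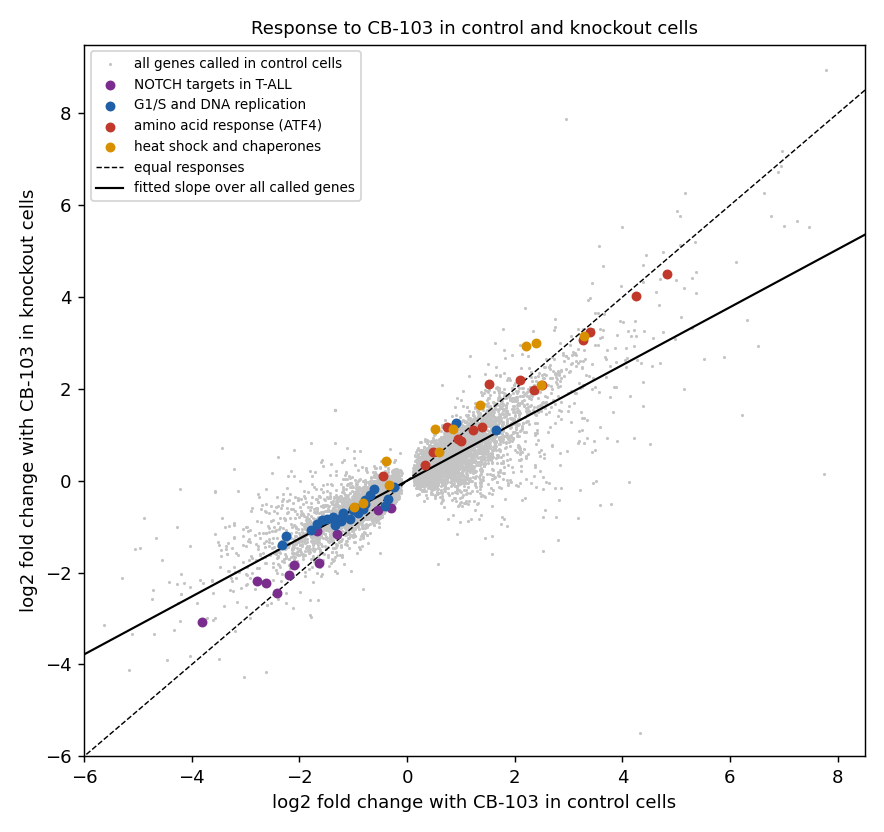
Log2 fold change with CB-103 in NT cells (x) and KO cells (y) of the 10095 genes called in NT cells, 4 of which lie outside the axes. Colours mark NOTCH targets, G1/S, amino acid response and heat shock genes; dashed, equal responses; solid, fitted slope of 0.63.

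Whether PIK3R1 loss changes the response to GSI was tested in the same way. HES1 fell further in KO cells, by -0.96±0.12 (n = 3 per group, adjusted p = 0.0014). NOTCH1 differed by -0.33±0.08 (adjusted p = 0.041), a call lost without NT DMSO replicate 1 (adjusted p = 0.095) or 3 (0.057), NT GSI replicate 1 (0.060) or 3 (0.12), KO DMSO replicate 1 (0.051), 2 (0.086) or 3 (0.088), or KO GSI replicate 1 (0.068), 2 (0.082) or 3 (0.077), in a fit to only the groups compared and in replicates 2 and 3 only (0.10). RXRA (2.12±0.19, adjusted p = 6.2e-05), KRT1 (1.62±0.16) and ACY3 (1.75±0.26) differed upward, as did the T-cell receptor chain CD3D (0.50±0.06). CCND3 (-0.12±0.10, adjusted p = 0.56) and DTX1 (0.30±0.12, adjusted p = 0.16) did not differ. MYC missed the threshold (0.33, adjusted p = 0.067). It was called without NT GSI replicate 2 or KO DMSO replicate 1, with the DESeq2 Wald test, the replicate block and gene sums, but not in replicates 2 and 3 only (0.074). Of 17346 genes, 484 were called, 364 upward (75.2%) and 120 downward, 54 at least 2-fold, of which 27 were upward and 27 downward. Without a count filter 287 were upward and 370 downward. The count hung on single libraries. It was 53, 140 or 214 without NT DMSO replicate 1, 2 or 3, and 107, 1505 or 168 without NT GSI replicate 1, 2 or 3. Without KO DMSO replicate 1, 2 or 3 it was 237, 177 or 488, and without KO GSI replicate 1, 2 or 3 it was 383, 114 or 69. With the replicate number as a block it was 1291. Ribosomal proteins held 6.78%, 7.92% and 7.23% of counts in NT GSI replicates 1, 2 and 3, in the reverse order of the mitochondrial shares of these libraries. Ribosomal proteins were upward for 9 of 36 (24 adjusted over the list alone; median 0.29, adjusted p = 6.7e-13, but adjusted p = 0.29 with an estimated correlation), and ribosome biogenesis for 6 of 30 (14 adjusted over the list alone; adjusted p = 1.2e-05, but adjusted p = 0.29 with an estimated correlation). The amino acid response was upward for 3 of 23 (4 adjusted over the list alone; adjusted p = 8.0e-04, but adjusted p = 0.29 with an estimated correlation).

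Responses were compared across all 17346 genes, which are not independent of each other. CB-103 responses of NT and KO cells correlated at r = 0.74, with 3613 genes higher in both (1276 if calls were independent), 3560 lower in both (1179), and 15 and 44 called in opposite directions. GSI responses of NT and KO cells correlated at r = 0.31 (0.76 among genes above the median expression), with 770 genes higher in both (162 if independent) and 1143 lower in both (249). The 2 inhibitors in NT cells correlated at r = 0.34, below the mean of 0.504 that simulated groups without any effect gave through their shared DMSO libraries, although the covariance of 0.182 exceeded the simulated 0.0692. In KO cells these values were r = 0.29, 0.485, 0.117 and 0.0670. In NT cells 1492 genes fell with both inhibitors (746 if independent) and 561 rose with CB-103 and fell with GSI (767). Pairs without shared libraries gave r = 0.092 (NT CB-103 with KO GSI; 0.16 among genes above the median expression and 0.054 by rank) and r = 0.16 (KO CB-103 with NT GSI).

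Transcripts of RB1, the retinoblastoma gene (chr 13, 48303726-48599436 in hg38), were examined after the gene's calls had been seen. The transcript at 48381250-48599436 stood at 158±5.8 TPM in NT DMSO, 38.4±5.2 in NT CB-103 and 48.1±5.95 in NT GSI, and at 0.632±0.37 TPM in KO DMSO, 0.321±0.32 in KO CB-103 and 0.0975±0.17 in KO GSI (n = 3 each). These values rest on few reads, 632±130 in NT DMSO and 2.25±1.1 in KO DMSO. The transcript at 48303726-48481890 stood at 83.7±2.8 TPM in NT DMSO and 94.6±1.9 in KO DMSO (8509±1066 and 8932±709 reads), at 62.4±2.8 in NT CB-103 and 71.2±5.8 in KO CB-103, and at 62.2±2.2 in NT GSI and 70.5±3.8 in KO GSI. No test was run on transcripts. In KO against NT DMSO the gene RB1 was called lower (-1.44±0.06, adjusted p = 4.8e-11), but not on gene sums of the transcript estimates (adjusted p = 0.48). In NT DMSO the transcript at 48381250-48599436 held 65.0% of the gene's TPM on its few reads. Deposited gene values lay closer to length-scaled TPM than to plain sums, so the call does not show a loss of RB1 reads.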

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

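Of the tests weighed with these values, the count of lists with a departing slope was chosen after the results were seen. So was the comparison of the heat shock slope with the G1/S slope. The others were chosen before. No prediction was written for the division of splits by their balance of genotypes. The interaction test marked 2533 genes whose response to CB-103 differed between the genotypes. Among the genes described, PIK3R1 differed by 0.81, CCND3 by 0.99, NOTCH1 by 0.58, DTX1 by 0.60 and CR2 by 0.73. PIK3R1 had fallen with CB-103 in NT cells and rose in KO cells (0.31, edgeR adjusted p = 0.0088). The others fell less in KO cells, where CCND3 (-0.54) and DTX1 (-1.12) already stood lower under DMSO. RRM2 (1.04), UHRF1 (0.94), MEOX1 (2.60), KRT1 (2.21), BCL2 (0.92), SPRED2 (1.66), ETV5 (1.5), CD2 (1.48) and PGK1 (0.71) differed in the same direction. The sterol genes HSD17B7 (-0.80) and STARD4 (-0.56) differed in the other direction. Lists that passed camera had medians of 0.38 (G1/S), 0.18 (G2/M), 0.36 (G1 cyclins and inhibitors), 0.40 (glycolysis), 0.41 (T-cell markers), 0.36 (T-ALL transcription factors), 0.33 (heat shock), 0.33 (interferon response), 0.16 (nucleotide and polyamine synthesis), 0.14 (ribosomal proteins), 0.076 (splicing factors) and -0.18 (cholesterol). None of these 12 lists passed with an estimated correlation, where adjusted p ranged from 0.248 to 0.508.

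For GSI the interaction test marked 484 genes. HES1 differed by -0.96, NOTCH1 by -0.33, RXRA by 2.12, KRT1 by 1.62, ACY3 by 1.75 and CD3D by 0.50. The call of NOTCH1 was lost without NT DMSO replicate 1 (adjusted p = 0.095) or 3 (0.057), NT GSI replicate 1 (0.060) or 3 (0.12), KO DMSO replicate 1 (0.051), 2 (0.086) or 3 (0.088), or KO GSI replicate 1 (0.068), 2 (0.082) or 3 (0.077). Lists that passed had medians of 0.29 (ribosomal proteins), 0.22 (ribosome biogenesis), 0.16 (nucleotide and polyamine synthesis), 0.19 (amino acid response), 0.17 (glycolysis), 0.14 (splicing factors), 0.17 (T-cell markers) and 0.39 (mitochondrially encoded genes), and none of the 8 passed with an estimated correlation (adjusted p 0.288 to 0.760). The mitochondrial list also lost its call with the replicate block (adjusted p = 0.057). The count of 484 became 53, 140 or 214 without NT DMSO replicate 1, 2 or 3, and 107, 1505 or 168 without NT GSI replicate 1, 2 or 3. It became 237, 177 or 488 without KO DMSO replicate 1, 2 or 3, and 383, 114 or 69 without KO GSI replicate 1, 2 or 3. With the replicate block it was 1291. NT GSI replicate 2, whose omission raised the count to 1505, had the lowest mitochondrial share of its group (1.90%).

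Other splits of the same libraries were drawn for the interactions. For CB-103, 6 of 100 splits, the real one included, gave at least 2533 genes (highest other 3770), and for GSI 10 of 100 gave at least 484 (highest other 3407). By this test alone a chance arrangement of libraries was not excluded for either count. All 5 and 9 other splits with as many genes placed the genotypes unequally on the sides compared, so that they carried the genotype difference itself. Among the 43 and 41 splits that balanced the genotypes, the highest counts were 1 and 1. These splits mixed NT and KO cells within groups, so the genotype difference widened the spread and kept such counts low in advance. They therefore decide nothing about the real counts.

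Genes called with CB-103 in NT cells responded less in KO cells, with a slope of 0.63 of KO on NT responses over 10095 genes. Choosing genes by their call in NT cells could lower this slope, but the reverse slope over the 8432 genes called in KO cells was 1.05, where selection alone would have put it below 1 as well. The slope was 0.629 with DESeq2 size factors, which decides nothing about scaling, since a library factor shifts all genes alike. Slopes of 22 lists ran from 0.246 to 1.04 and departed from that of all called genes in 9, 8 of them above it. Others such as G1/S (0.628) lay close to it. This count decides little about a uniformly weaker exposure of KO cells to CB-103. Its tolerance was set after the results were seen, and the slope of all called genes includes weakly expressed genes, whose noise can lower it. Lists also differed from each other. Heat shock, the highest of the 22, stood at 1.04 and G1/S at 0.628. Their SDs over replicates left out, taken on log2 CPM differences, were 0.015 and 0.013. This pair was picked after the slopes were seen, and the SDs do not cover the choice of lists or of their genes. The pair therefore does not exclude an equal scaling of all responses. What stays open is a weaker exposure, either uniform or met by lists with different sensitivity. Also open is whether the lower slope comes from loss of PIK3R1 or from other differences of a single KO line. A rescue with PIK3R1 or a second guide would separate these.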

How the results depend on the processing

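Of the settings described here, the fit to replicates 2 and 3 only was chosen after the data were seen, and the others beforehand. Counts of called genes moved by more than 1.5 times when a 2-fold change was required: to 3101 from 10095 (NT CB-103), 510 from 4277 (NT GSI), 1712 from 8432 (KO CB-103), 322 from 3341 (KO GSI), 580 from 3720 (KO against NT DMSO), 926 from 6412 (KO against NT CB-103), 797 from 5861 (KO against NT GSI), 2768 from 9765 (CB-103 against GSI in NT), 1700 from 8302 (the same in KO), 303 from 2533 (CB-103 interaction) and 54 from 484 (GSI interaction). The GSI interaction also moved with the DESeq2 Wald test (1257), gene sums of transcript estimates (997), the replicate block (1291, with all 484 among them) and replicates 2 and 3 only (42, of which 36 were shared). Its share of upward genes was 75.2%, against 43.7% without a count filter, 60.4% on gene sums and 97.6% in replicates 2 and 3. The cause was not tested.

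Leaving out 1 library at a time gave 9443 to 9874 genes for NT CB-103, 3234 to 4206 for NT GSI, 7685 to 8009 for KO CB-103, 2472 to 2817 for KO GSI, 2944 to 3298 for KO against NT DMSO, 5352 to 6141 for KO against NT CB-103, 4711 to 5840 for KO against NT GSI, 9194 to 9380 and 7598 to 7818 for CB-103 against GSI in NT and KO, 1833 to 2751 for the CB-103 interaction and 53 to 1505 for the GSI interaction. PIK3R1 in KO against NT DMSO ranged from -1.0 to -0.94.

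In KO against NT DMSO, HES1 was not called (-0.21, adjusted p = 0.079), but was called without KO DMSO replicate 1 (-0.31, adjusted p = 0.014), with limma-voom (adjusted p = 0.034), with the block (0.031) and in replicates 2 and 3 (-0.36, adjusted p = 0.0052). MYC was not called (-0.16, adjusted p = 0.093), but was called without KO DMSO replicate 1 (-0.24, adjusted p = 0.0079), with the block (adjusted p = 0.030) and in replicates 2 and 3 (-0.25, adjusted p = 0.017). On gene sums 4 values changed sign: RB1 in KO against NT CB-103 (0.12) and in KO against NT GSI (0.15), IGF1R in NT CB-103 against NT GSI (-0.21) and MDGA1 in the CB-103 interaction (0.17).

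Same-numbered libraries did not pair in 3 comparisons. For KO and NT DMSO the correlations were 0.523, 0.127 and 0.038, with a higher value for another number in replicates 2 (0.339) and 3 (0.334). For KO and NT GSI they were 0.281, -0.039 and 0.111 (higher for another number in replicates 2, 0.234, and 3, 0.124), and for CB-103 and GSI in NT cells 0.257, 0.017 and 0.199 (0.235 for another number in replicate 2). The replicate block gave 4412, 6699 and 10209 genes there.

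Of 286 list tests, 122 passed camera, 18 of them also with an estimated correlation, 117 with fry for a common direction (188 in all), 120 with fry for mixed directions (245), 119 with the block (121) and 122 with size factors (124). None of the 122 main calls had the opposite direction under another setting, apart from fry for mixed directions, which gives no direction. The block ended G1 cyclins in KO GSI (adjusted p = 0.059), MAPK feedback in KO against NT GSI (0.060) and the mitochondrial list in the GSI interaction (0.057), and added glycolysis in KO against NT DMSO (0.022) and heat shock in KO against NT CB-103 (0.033). It changed no other call of a list.

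Correlations of responses moved with the genes used. Among genes above the median expression they were 0.23 (CB-103 with GSI, NT), 0.27 (the same, KO), 0.94 (CB-103, NT with KO), 0.76 (GSI, NT with KO), 0.16 (NT CB-103 with KO GSI) and 0.22 (KO CB-103 with NT GSI). By rank they were 0.30, 0.27, 0.75, 0.33, 0.054 and 0.12.

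Each comparison of 2 groups has only 10 splits of its libraries, too few for a share under 0.05. The real split was the only 1 of 10 with as many calls in each of the 9. The highest other count was 1 for NT GSI, KO against NT DMSO and CB-103 against GSI in NT cells, and 0 for the others.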

Other observations

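The share of knockout genes, the MYC test and the strand test of covered genes were chosen after the results were seen. So was the comparison of NOTCH target medians between the inhibitors. Other tests in this part were chosen before. CB-103 raised JUN from 1.81±0.21 to 19.4±1.2 CPM in NT cells and from 1.36±0.33 to 21.3±0.53 CPM in KO cells, and lowered SPRED2, which restrains MAPK signalling, 8.33-fold in NT and 2.63-fold in KO cells. The proapoptotic BBC3 rose in NT (0.837±0.085 to 10.2±0.62 CPM) and 9.91-fold in KO cells, while BCL2L11, another proapoptotic gene, fell 3.31-fold and 2.54-fold. PMAIP1 rose with CB-103 in KO cells (58.6±1.8 to 128±11 CPM) and fell with GSI in NT cells (50.8±0.88 to 33.4±1.6 CPM). GADD45A likewise rose 2.31-fold with CB-103 in KO cells and fell 1.90-fold with GSI.

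The terminal transferase DNTT stood at 187±22 CPM with CB-103 and 1043±45 CPM with GSI in NT cells, and at 259±11 and 922±10 CPM in KO cells. LYL1 rose 1.71-fold with GSI in NT cells and fell 2.62-fold with CB-103. The receptor constant gene TRAC rose with GSI in KO cells from 0.160±0.030 to 2.83±0.20 CPM. IFI44 rose with CB-103 in both genotypes (3.22-fold and 3.91-fold), whereas OAS3 fell 3.14-fold in NT cells. The regulatory gene PIK3R6 was 3.01-fold higher in KO than in NT cells under DMSO, from 0.50±0.072 CPM, and the insulin receptor substrate IRS2 1.75-fold lower.

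Amino acid response genes fell with GSI and rose with CB-103. If vehicle libraries of NT cells had been out of place, KO cells would not have shown it, but 18 of 23 genes fell with GSI there as well. Without the GSI library that stands apart in mitochondrial share, 19 still fell in NT cells. Loss of MYC as the shared driver of both was argued against, since MYC fell in all 4 comparisons with DMSO (closest to 0 at -1.63) while the list moved in opposite directions, and MYC as the driver of 1 of them was not tested. In NT cells the median fall of NOTCH targets was alike with both inhibitors (-1.895 with CB-103 and -1.823 with GSI). Single targets did not fall alike: in the direct comparison above, some stood higher with CB-103 and as many stood lower. The amino acid list nevertheless had medians of 0.94 with CB-103 and -0.60 with GSI. These medians argue only against the common fall of the NOTCH list as the sole cause of the rise. Whether a deeper fall of single targets with CB-103 plays a part was not tested. Whether another action of CB-103 causes the rise, or an action of GSI hides it, was not tested, and cells without RBPJ treated with CB-103 would tell.

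Libraries of replicate 1 stood apart in every group. Weaker strand specificity could raise genes lying opposite abundant ones. The median difference of 254 covered genes was 0.123, above the -0.037 that was the highest of 1000 random lists but too small to decide. Across these genes the difference rose with the ratio of the partner's level to the gene's own (Spearman 0.417). A low level of the gene itself also raises this ratio. GC content was left undecided (-0.106). Between replicates 2 and 3, edgeR called 0 genes, with 633 at an unadjusted p under 0.05, and no other tool was run on them. Strand-specific alignment of the reads would settle the matter.

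The smaller fall of CCND3 with CB-103 in KO cells (0.99) combined a lower level under DMSO (-0.54) with a higher level under CB-103 (0.44). Whether signalling through PI3K affects its transcription when the NOTCH complex is blocked was not tested, and PI3K inhibitors in these cells would show it. NOTCH1 RNA fell with CB-103 in NT and KO cells, and an action on autoregulation of NOTCH1 would be tested by occupancy of its enhancers. The KO line had almost no VASH1 and little of the RB1 transcript at 48381250-48599436 in any treatment, and whether this came from PIK3R1 loss or from the origin of the line was not tested; independent guides would show it.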
